A study of Homo sapiens with 6 samples.

How the data were processed

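RNA was measured in MCF-7 cells, an estrogen receptor-positive human breast cancer line, after transfection with an siRNA against PSF (gene SFPQ), an siRNA against NONO, or a control siRNA. Cells were kept in medium without phenol red and with charcoal-stripped serum, which lowers background estrogen. They then received 10 nM 17β-estradiol (E2) or ethanol vehicle for 12 h, per the labels' protocols. Biotinylated cRNA was made from 150 ng of total RNA. The 3 siRNAs and 2 hormone states gave 6 groups with 1 array each, on a whole-transcript gene array.

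The deposited values were log2 expression values, 1 per probe set and array. They were made with RMA in Affymetrix Expression Console, per the submitters' processing notes; versions and the genome build were not given in the sources used here. RMA corrects the background, quantile-normalizes the arrays and summarizes probes into probe sets, so a shift of all transcripts between groups would not show in these values. Array medians ran from 5.81 to 5.84, and Pearson correlations between arrays, across probe sets, from 0.988 to 0.993. For arrays, their number limits the precision. The target genes' own levels on each array were used to check the labels.

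The table held 33297 probe sets. The platform annotation gave 1 gene for 19460 of them, several genes for 1754 and no gene for 12083. The gene IDs of 19429 of the 1-gene probe sets were found in the RefSeq gene table of GRCh38.p14, which was used for current names alone, and those of 31 were not. No coordinates or gene lengths were used. Probe sets with several genes or none were named nowhere. The probe set with the highest mean stood for each gene. Genes with a mean log2 level below 4.08, the 25th percentile of all probe sets, were left out. This left 15405 genes.

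The 4 contrasts were fitted with limma 3.58.1 in R 4.3.3 on all 6 arrays, as an additive model of siRNA and hormone, with eBayes and Benjamini-Hochberg adjustment at 0.05. The contrasts were siPSF minus siControl, siNONO minus siControl, siPSF minus siNONO, and E2 minus vehicle. No group had a replicate, so the 2 hormone states stood in for replicates of an siRNA, and the 3 siRNAs for replicates of a hormone state. Any interaction of siRNA and hormone therefore counted as residual error, on 2 residual and 3.94 prior degrees of freedom. The labels do not say that arrays came from separate cultures, so p-values of single genes measure the spread between these arrays, which may be technical. The interaction itself left no residual degrees of freedom and had no test. For it, the median of a gene list is given with its percentile among 10000 random lists of the same size matched on mean expression.

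Before the data were examined, 16 gene lists were fixed for testing. They covered estrogen-induced genes, estrogen-repressed genes, DNA replication and E2F targets, mitosis, paraspeckle components, splicing factors, genes of long genomic span, p53 targets, the unfolded protein and amino acid stress response, interferon-stimulated genes, luminal markers, basal and mesenchymal markers, cholesterol synthesis, hypoxia, the circadian clock and ribosomal proteins. Members came from general knowledge of these pathways, and 363 of 407 list entries, targets and study genes included, were among the tested genes. The paraspeckle list holds the targets SFPQ, NONO and PSPC1. A further list of study genes (ESR1, SCFD2, SKP2 and E2F8) was not tested as a set. Lists were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over all 64 list tests. The same test with an estimated correlation, and fry, stood beside it. At the preset correlation, camera takes its degrees of freedom from the number of genes. Very small list p-values therefore rest on the spread between genes and are not evidence from replicate arrays. With an estimated correlation, camera takes its p-value on the 2 residual degrees of freedom, so it has little power here. A call lost in that form need not be lost to correlation between genes.

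Named genes followed a rule fixed before the data were examined. For each contrast, these were the 10 genes with the largest positive and the 10 with the largest negative log2 difference among those called in the same direction in every pair of arrays. To these were added the targets and study genes, 2 to 4 members of each list with the largest differences, and list members given as context. Small RNAs and genes with locus or reading-frame codes could be counted without being named. Fold sizes were also counted without a test, as genes differing at least 2-fold the same way in both hormone states, or in all 3 siRNAs.

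The pipeline was tested on simulated data for the 15405 genes. Of 100 genes given a log2 change of 0.5, it recovered 84 for siPSF minus siControl, 80 for siNONO minus siControl, 76 for siPSF minus siNONO and 96 for E2 minus vehicle. At a log2 change of 1 it recovered 99, 100, 100 and 100. In the same runs it also called 18, 27, 15 and 18 unchanged genes, a share of the calls above the 0.05 threshold in each contrast. With no change simulated it called 0, 2, 0 and 0 genes. Simulated genes varied independently, with the spread estimated by eBayes, and carried no effect besides the tested one. Real genes can vary together between arrays, so recovery and false calls on these arrays may differ. Alternatives covered quantile normalization, median centring and cyclic loess, no or a stricter filter on dim genes, the mean of a gene's probe sets, an intensity trend, robust eBayes, the arrays of the compared siRNAs alone, fits without the covariate, and leaving out each array in turn. A fit of all probe sets above the dim cutoff together was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.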

Results

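The series measured RNA levels in MCF-7 cells with siRNA against PSF or NONO, with and without E2. PSF (encoded by SFPQ) and NONO belong to a family of nuclear RNA- and DNA-binding proteins with PSPC1, and the 3 are core proteins of paraspeckles. Each of the 6 combinations of siRNA and hormone state had 1 array, with no replicates. Differences are given on the log2 scale as the mean over the paired arrays, with the standard error (SE) of the limma fit. Adjusted p-values are from limma for genes and from camera for gene lists.

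Each siRNA lowered its own target. SFPQ stood at log2 10.13 with vehicle and 10.29 with E2 under siControl, at 9.05 and 8.91 under siPSF, and at 10.36 and 10.50 under siNONO. That was a difference of -1.23 (SE 0.10, adjusted p = 0.0107) for siPSF, which left 42.6% of the siControl level. NONO stood at 10.77 and 10.86 under siControl, at 9.12 and 9.13 under siNONO, and at 11.01 and 10.87 under siPSF. The siNONO difference was -1.69 (SE 0.09, adjusted p = 0.00684), which left 30.9%. PSPC1, the remaining family member, rose under both, by 0.64 under siPSF (SE 0.08, adjusted p = 0.017) and by 0.58 under siNONO (SE 0.08, adjusted p = 0.0162). The difference between the knockdowns for PSPC1 was 0.06 (adjusted p = 0.655). Without either siControl array or either array of the knockdown, limma left 0 calls against siControl, with 2044 to 2883 genes for siPSF and 2595 to 2873 for siNONO at an unadjusted p under 0.05. The largest adjusted p was then 0.104 for SFPQ under siPSF and 0.0717 for NONO under siNONO. For PSPC1 it was 0.142 under siPSF and 0.135 under siNONO.

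**Figure D1:**
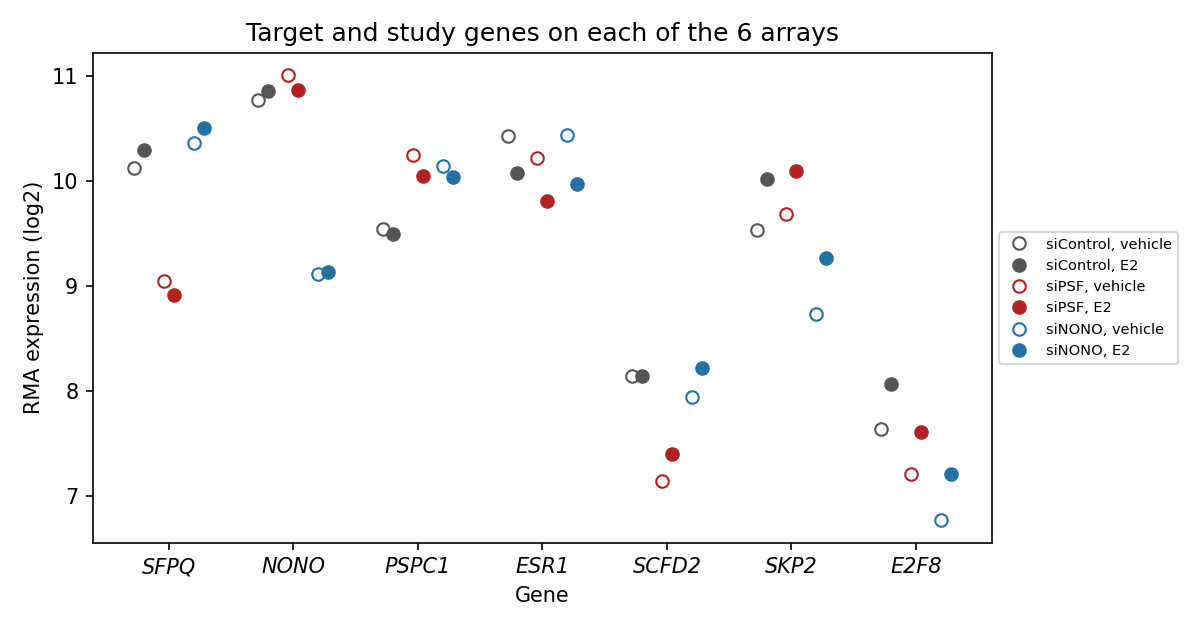
RMA expression (log2, vertical axis) of the 3 family members and the 4 study genes (horizontal axis) on each of the 6 arrays. Open points are vehicle, filled points E2, and colours mark the siRNA. Each point is 1 array, so there are no error bars. SFPQ is lowest on both siPSF arrays (9.05 and 8.91) and NONO on both siNONO arrays (9.12 and 9.13).

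The 4 study genes were picked from what is known of the study, which may have chosen them on these samples, so their direction is not independent evidence. SCFD2, which encodes a Sec1 family domain protein, fell under siPSF by 0.87 (SE 0.10, adjusted p = 0.0137), from 8.14 in both hormone states to 7.14 with vehicle and 7.40 with E2. Under siNONO its difference was -0.06 (adjusted p = 0.758), and the direct contrast of the knockdowns was -0.82 (adjusted p = 0.00614). SKP2, a ubiquitin ligase subunit that promotes entry into S phase, fell under siNONO by 0.78 (SE 0.08, adjusted p = 0.00793) and differed by 0.11 under siPSF (adjusted p = 0.457). E2F8, a cell cycle transcription factor, fell under siPSF by 0.45 (adjusted p = 0.033) and under siNONO by 0.86 (adjusted p = 0.0069). Without either siControl array or either array of the knockdown, the largest adjusted p was 0.104 for SCFD2 under siPSF, 0.0827 for SKP2 under siNONO and 0.0717 for E2F8 under siNONO. The siPSF call of E2F8 was lost without any 1 of the 6 arrays (adjusted p 0.0666 to 0.221) and with the 4 arrays of the compared siRNAs (adjusted p = 0.0666; range over planned settings that kept all arrays or these 4, 0.00729 to 0.532). ESR1, which encodes the estrogen receptor α, stood at 10.43 and 10.08 under siControl and at 10.22 and 9.81 under siPSF. That difference of -0.24 did not pass (SE 0.08, adjusted p = 0.154), though it did with an intensity trend in the variances (adjusted p = 0.0195; range over such settings 0.0195 to 0.749). Averaging in a dimmer ESR1 probe set gave -0.09. With E2, ESR1 fell by 0.41 (adjusted p = 0.0192), SKP2 rose by 0.48 (adjusted p = 0.0136) and E2F8 by 0.42 (adjusted p = 0.0155). Leaving out any of the 6 arrays ended the E2 calls of ESR1 (adjusted p 0.0666 to 0.0986) and E2F8 (0.0565 to 0.102). That of SKP2 ended without either siControl array (adjusted p = 0.0899) or either siNONO array (adjusted p = 0.0742). Adjusted over the list alone, SCFD2 and E2F8 passed under siPSF and so did ESR1 (adjusted p = 0.0295), which is not independent evidence.

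More genes were lower than higher under siPSF. In siPSF minus siControl, 549 genes were lower and 216 higher of 15405. Among the largest falls were PLPPR5 (-1.79, SE 0.11), a brain-type phospholipid phosphatase-related protein, and PLS3 (-1.55, SE 0.08), an actin-bundling protein. ST8SIA6, CACNG4, KIF5C, FAM216A, FAR2, LINC00314, PLCB1 and ATXN7L1 fell by 1.39 to 1.51. KIF5C is a kinesin motor and PLCB1 a phospholipase C. Among the largest rises were CYP4Z2P (1.75, SE 0.25), a pseudogene whose close copy CYP4Z1 makes its level uncertain, and HMOX1 (1.66, SE 0.09), which encodes heme oxygenase 1. TARP, TP53INP1, SPRY4, SLC6A19 and DDIT4 rose by 1.14 to 1.46. TP53INP1 is a p53-induced stress gene, SPRY4 an inhibitor of receptor kinase signalling, and DDIT4 an inhibitor of mTOR. Adjusted p-values of these genes lay between 0.00743 and 0.0263. At least 2-fold in both hormone states, without a test, 31 genes were lower and 12 higher.

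Genes of long genomic span fell as a group under siPSF. Of 35 measured, 17 fell, 0 rose and 18 did not pass; adjusted over the list alone, 22 fell. The median difference was -0.38 (adjusted p = 3.3e-14; adjusted p = 0.299 with an estimated correlation). NAALADL2 (-1.25), the receptor tyrosine kinase gene ERBB4 (-1.16), THSD4 (-0.89) and the tumour suppressor WWOX (-0.82) moved furthest. The list median was -0.39 with vehicle and -0.35 with E2.

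Most estrogen-responsive genes did not pass under siPSF, though both of their lists were called by camera. Of 35 estrogen-induced genes, 3 fell (MYBL1 by 0.73, STC2 by 0.54, NHERF1 by 0.52), SLC7A5 rose by 0.45 and 31 did not pass; over the list alone 4 fell and 1 rose. Their median was -0.16 (adjusted p = 0.00286; adjusted p = 0.459 with an estimated correlation). Of 16 estrogen-repressed genes, 4 rose, 1 fell and 11 did not pass; over the list alone 7 rose and 3 fell. TP53INP1 (1.25), the prostate stem cell antigen gene PSCA (0.72) and the receptor gene ERBB2 (0.65) were among the 4, and the median was 0.30 (adjusted p = 0.0015; adjusted p = 0.522 with an estimated correlation). The gene that fell was BCAS1 (-0.43). By fry neither list was called (adjusted p = 0.104 for estrogen-induced and 0.134 for estrogen-repressed genes). The mitosis list had a median of -0.17, with 28 of 29 genes below 0, though just 1, the checkpoint gene MAD2L1 (-0.45), passed, also over the list alone (adjusted p = 6.36e-06; adjusted p = 0.522 with an estimated correlation). The p53 targets had a median of 0.17 (adjusted p = 0.00121; adjusted p = 0.337 with an estimated correlation). Of 23, PHLDA3 (0.59) and SESN2 (0.53) rose, by either adjustment. By fry neither the mitosis list (adjusted p = 0.116) nor the p53 list (adjusted p = 0.0751) was called. Replication and E2F targets had a median of -0.02 (adjusted p = 0.337), with 1 of 37 higher and 1 lower.

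Leaving out siPSF with E2 ended the call of the estrogen-induced list and moved its median from -0.16 to -0.09. Without siControl with E2 the median was also -0.09, though the call was kept. The p53 median was 0.10 without siPSF with vehicle. Leaving out siControl with E2 ended that of the estrogen-repressed list (adjusted p = 0.0738; range 3.3e-05 to 0.0738). Leaving out either siControl array or either siPSF array left limma with 0 calls, with 2044 to 2883 genes at an unadjusted p under 0.05, against 3306 with all arrays. Leaving out either siNONO array gave 111 higher and 333 lower. A fit of all 24973 probe sets above the dim cutoff, chosen after seeing the data, also called 0 genes, with 2756 at an unadjusted p under 0.05.

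**Figure D2:**
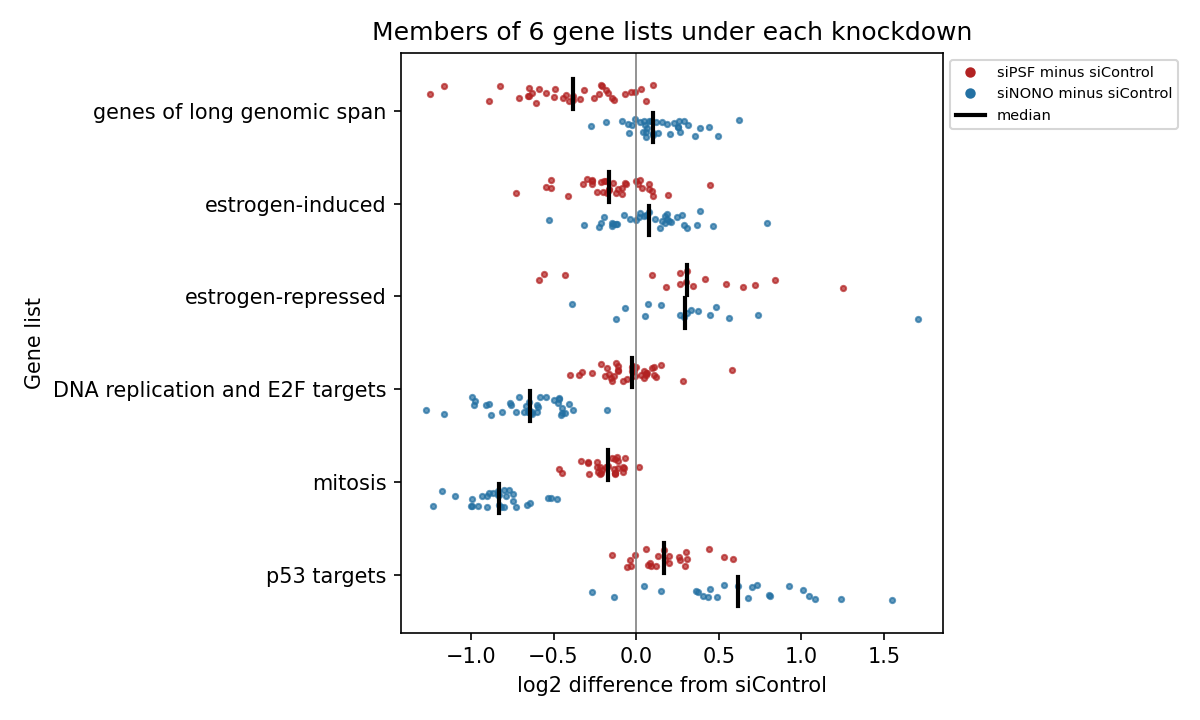
Difference from siControl (log2, horizontal axis) of each measured member of 6 gene lists (vertical axis), siPSF in red and siNONO in blue, as the mean of the 2 hormone states. Black bars are medians; points are spread vertically for display. Long-span genes have medians of -0.38 under siPSF and 0.10 under siNONO, and mitosis genes of -0.17 and -0.83.

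Cell cycle genes were lower and p53 targets higher under siNONO. In siNONO minus siControl, 737 genes were lower and 528 higher. Besides NONO itself, the largest falls were MSMB (-1.67, SE 0.23), which encodes a secreted β-microseminoprotein, and CEP55 (-1.58, SE 0.12), an abscission protein. DDIAS, UHMK1, SHCBP1, EXO1, EFEMP1, EPB41L2 and CDK1 fell by 1.23 to 1.41. EXO1 is a DNA exonuclease and CDK1 the mitotic kinase. The largest rises were EDA2R (1.77, SE 0.08), a p53-regulated receptor of the tumour necrosis factor family, TP53INP1 (1.71, SE 0.17) and the p53 target SPATA18 (1.55, SE 0.08). SCN1A, GDAP1, TMEM229B, the DNA damage recognition gene DDB2, YPEL2, CDH18 and the interferon-induced IFIT1 rose by 1.21 to 1.53. Adjusted p-values of these genes lay between 0.00684 and 0.0189. At least 2-fold in both hormone states, 31 genes were lower and 11 higher.

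Of 37 replication and E2F targets, 34 fell under siNONO, 0 rose and 3 did not pass; over the list alone 36 fell. EXO1 (-1.27), the origin recognition gene ORC1 (-1.16), the ubiquitin ligase adaptor gene DTL and RRM2 (-0.98), a ribonucleotide reductase subunit, fell most. The median was -0.64 (adjusted p = 2.46e-27; adjusted p = 0.313 with an estimated correlation). Of 29 mitosis genes, 28 fell and 1 did not pass, and all 29 fell over the list alone. CDK1 (-1.23), the mitotic transcription factor FOXM1 (-1.18) and the securin gene PTTG1 (-1.10) led them, and the median was -0.83 (adjusted p = 3.64e-27; adjusted p = 0.313 with an estimated correlation). Of 23 p53 targets, 15 rose, 0 fell and 8 did not pass; over the list alone 19 rose and 1 fell. SPATA18 (1.55), DDB2 (1.24), the sestrin gene SESN2 (1.08) and ZMAT3 (1.04) rose most, and the median was 0.62 (adjusted p = 5.5e-13; adjusted p = 0.313 with an estimated correlation).

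A further 3 lists shifted under siNONO. Estrogen-repressed genes had a median of 0.30 (adjusted p = 0.000971; adjusted p = 0.522 with an estimated correlation). Of 16, 4 rose (6 over the list alone), with TP53INP1 (1.71), BCAS1 (0.73) and PIK3IP1 (0.56) furthest up. By fry neither this list (adjusted p = 0.125) nor splicing factors (adjusted p = 0.104) were called, while long-span genes were (adjusted p = 0.0172). Long-span genes had a median of 0.10 (adjusted p = 0.0015; adjusted p = 0.321 with an estimated correlation). Of 35, 4 rose, among them ERBB4 (0.50), the fragile-site gene FHIT (0.44) and NBEA (0.39); over the list alone 7 rose and 1 fell. Splicing factors had a median of -0.15 (adjusted p = 0.0113; adjusted p = 0.522 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.0793; range over settings 0.00714 to 0.522). It was also lost without siControl with E2 (median -0.09, adjusted p = 0.173) or siNONO with E2 (adjusted p = 0.0662), and the estrogen-repressed call without siControl with E2 (adjusted p = 0.089; range over arrays left out 3.23e-06 to 0.089). The splicing repressor gene PTBP1 (-0.55) and TRA2B (-0.36) fell while the paralog PTBP2 rose by 0.67, of 35 measured; over the list alone 3 fell and 1 rose. Leaving out either siControl or either siNONO array left limma with 0 gene calls, with 2595 to 2873 genes at an unadjusted p under 0.05, against 4028 with all arrays. The fit of all probe sets called 69 genes higher and 218 lower.

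The direct contrast of the knockdowns, which used none of the siControl levels, called the most genes. In siPSF minus siNONO, 1105 genes were higher and 1397 lower. NONO itself and SALL4 (1.73, SE 0.07), a stem cell transcription factor, had the largest positive differences. PLEKHS1, MSMB, TARP, FLVCR2, LITAF, SPRY4, HMOX1 and CYP4Z2P followed at 1.34 to 1.64. The most negative were the mucin gene MUC15 (-2.11, SE 0.09) and GDAP1 (-1.99, SE 0.09), followed by SLC24A3, NAALADL2, NR5A2, SCN1A, ST8SIA6, CDH18, SLC4A10 and ATXN7L1 at -1.91 to -1.69. Adjusted p-values of these genes lay between 0.00236 and 0.0204. The MSMB call was lost without siPSF with vehicle (adjusted p = 0.0648), siPSF with E2 (adjusted p = 0.0785) or siNONO with vehicle (adjusted p = 0.0531). That of CYP4Z2P was lost without siPSF with vehicle (adjusted p = 0.123) or siPSF with E2 (adjusted p = 0.0858), and its difference was 0.85 without siNONO with vehicle.

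Between the knockdowns, 36 of 37 replication genes were higher under siPSF (37 over the list alone), with a median of 0.62 (adjusted p = 1.14e-21; adjusted p = 0.313 with an estimated correlation). So were 26 of 29 mitosis genes (28 over the list alone), with a median of 0.62 (adjusted p = 5.63e-18; adjusted p = 0.332 with an estimated correlation). Of 35 long-span genes 24 were lower (30 over the list alone, with 1 higher), with a median of -0.49 (adjusted p = 3.86e-14; adjusted p = 0.299 with an estimated correlation). NAALADL2 (-1.87) and ERBB4 (-1.66) differed most. Of 23 p53 targets 12 were lower and 1 higher (14 and 1 over the list alone), with a median of -0.37 (adjusted p = 7.57e-07; adjusted p = 0.313 with an estimated correlation). SPATA18 (-1.25) and ZMAT3 (-1.08) differed most. Of 35 estrogen-induced genes 7 were lower (11 over the list alone), with a median of -0.19 (adjusted p = 0.000844; adjusted p = 0.449 with an estimated correlation). CXCL12 (-1.12), which encodes a chemokine, and GREB1 (-0.98), an estrogen receptor cofactor, differed most. The list's median was -0.11 without siPSF with E2 or siNONO with E2. It was not called by fry (adjusted p = 0.0861), while the other called lists of this contrast were. The unfolded protein and amino acid stress list had a median of 0.23, with 5 of 20 higher, TRIB3 (0.76) furthest, and 2 lower; over the list alone 7 were higher and 3 lower (adjusted p = 0.0442; adjusted p = 0.449 with an estimated correlation). That call was lost with the mean of each gene's probe sets (adjusted p = 0.0584; range over settings 0.0133 to 0.449), without siPSF with E2 (adjusted p = 0.0891) and without siNONO with E2 (adjusted p = 0.132). Leaving out siPSF with vehicle gave 379 genes higher and 491 lower, siPSF with E2 348 and 506, siNONO with vehicle 302 and 392, and siNONO with E2 305 and 457. The fit of all probe sets gave 501 and 649.

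E2 induced known hormone targets under all 3 siRNAs. In E2 minus vehicle, 774 genes were higher and 596 lower. GREB1 rose by 2.89 (SE 0.11), which is 7.39-fold, and IL20 by 2.87 (SE 0.18). CXCL12, the transcription factor gene EGR3, PKIB, SYTL5, NPY1R, the progesterone receptor gene PGR, PTGES and RBM24 rose by 1.84 to 2.35. CYP1A1 (-1.37, SE 0.15), a xenobiotic-metabolizing enzyme, fell most. TRERF1, IL1R1, TGFB3, TP53INP1, CREBRF, ST8SIA4, LIPH, BLNK and ID2 fell by 1.07 to 1.31. Adjusted p-values of these genes lay between 0.000911 and 0.0111. The call of IL1R1 was lost without either siControl array (adjusted p = 0.0663), of TP53INP1 without either siPSF array (adjusted p = 0.0528) and of BLNK without either siNONO array (adjusted p = 0.0529). At least 2-fold under all 3 siRNAs, 36 genes were higher and 3 lower.

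Of 35 estrogen-induced genes, 30 rose with E2 (33 over the list alone), with a median of 0.90 (adjusted p = 2.38e-29; adjusted p = 0.299 with an estimated correlation). Of 16 estrogen-repressed genes, 13 fell (14 over the list alone), with a median of -0.74 (adjusted p = 4.75e-12; adjusted p = 0.337 with an estimated correlation). Of 37 replication and E2F targets, 31 rose (37 over the list alone), led by DTL (1.34), the licensing factor gene CDC6 (1.11) and MCM10 (1.10), with a median of 0.56 (adjusted p = 2.5e-27; adjusted p = 0.313 with an estimated correlation). Of 15 cholesterol synthesis genes, 7 rose (11 over the list alone), with a median of 0.27 (adjusted p = 3.34e-06; adjusted p = 0.313 with an estimated correlation). The mitosis list had a median of 0.08, and MAD2L1 (0.40), TOP2A (0.33) and BUB1B (0.30) rose of 29, also over the list alone (adjusted p = 0.00732; adjusted p = 0.594 with an estimated correlation). That call was lost without siNONO with vehicle (adjusted p = 0.125) or siNONO with E2 (adjusted p = 0.132), with a median of 0.05 in both cases. Without either siPSF array the median was 0.14. Neither the mitosis list (adjusted p = 0.192) nor the estrogen-repressed list (adjusted p = 0.0515) was called by fry, while the other called lists were. Long-span genes had a median of -0.08, with 6 lower and 2 higher of 35 (10 and 3 over the list alone; adjusted p = 0.0039; adjusted p = 0.332 with an estimated correlation). NBEA (-0.93) and ERBB4 (-0.74) moved furthest. Leaving out either siControl array gave 135 higher and 56 lower, either siPSF array 293 and 207, and either siNONO array 216 and 112, since each leaves 1 siRNA without a pair. The fit of all probe sets gave 195 and 95.

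Whether each knockdown altered the E2 response was not testable with 1 array per group, so values are given. The median response of the 35 estrogen-induced genes was 0.96 under siControl, 0.75 under siPSF and 0.82 under siNONO. Among the brighter genes, those at or above the median of all probe sets, the siControl and siPSF medians were 0.76 and 0.74. Gene by gene over all 35, the median difference from siControl was -0.08 under siPSF, at percentile 0.88 of matched random lists, and 0.00 under siNONO, at percentile 56.2. Low percentiles under siPSF were not particular to this list. Replication genes lay at 0.03, mitosis genes at 0.04 and splicing factors at 0.07. RAPGEFL1 responded by 2.05 under siControl, 1.22 under siPSF and 2.09 under siNONO. KCNK5 responded by 1.34, 0.66 and 0.71 in that order, so it was smaller under both knockdowns. PGR responded by 2.25, 1.68 and 2.05 in that order. GREB1 responded by 2.84, 3.18 and 2.63, so the list did not move as one. The median response of the 16 estrogen-repressed genes was -0.82 under siControl, -0.65 under siPSF and -0.59 under siNONO. Gene by gene, the median difference from siControl was 0.37 under siPSF (percentile 100 of matched lists) and 0.16 under siNONO (percentile 99.7). Directly between the knockdowns, siPSF minus siNONO, it was 0.08 (percentile 88.4). High percentiles against siControl were not particular to this list either. Under siPSF and siNONO, interferon-stimulated genes lay at 99.8 and 99.6, and luminal markers at 97.1 and 99.8. TGFB2 responded by -0.56 under siControl, 0.03 under siPSF and 0.28 under siNONO, and TP53INP1 by -1.55, -1.12 and -0.80. CYP1A1 responded by -1.63, -0.91 and -1.57, and BLNK by -1.43, -0.72 and -1.12. The smaller repression was thus not particular to siPSF. Both knockdowns were set against the same siControl arrays, so a large fall on those arrays alone would make both responses look smaller. An effect of either knockdown on repression cannot be told apart from that. In sets chosen after seeing the data, genes that moved at least 2-fold under a single siRNA were compared between the others. Picked under siNONO, 91 rises had a mean response of 0.99 under siPSF and 1.13 under siControl, and 25 falls -0.65 and -0.95. Picked under siPSF, 58 rises averaged 1.29 under siNONO and 1.27 under siControl, and 17 falls -0.66 and -0.88. Picked under siControl, 68 rises averaged 1.12 under siPSF and 1.37 under siNONO, and 31 falls -0.73 and -0.82.

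**Figure D3:**
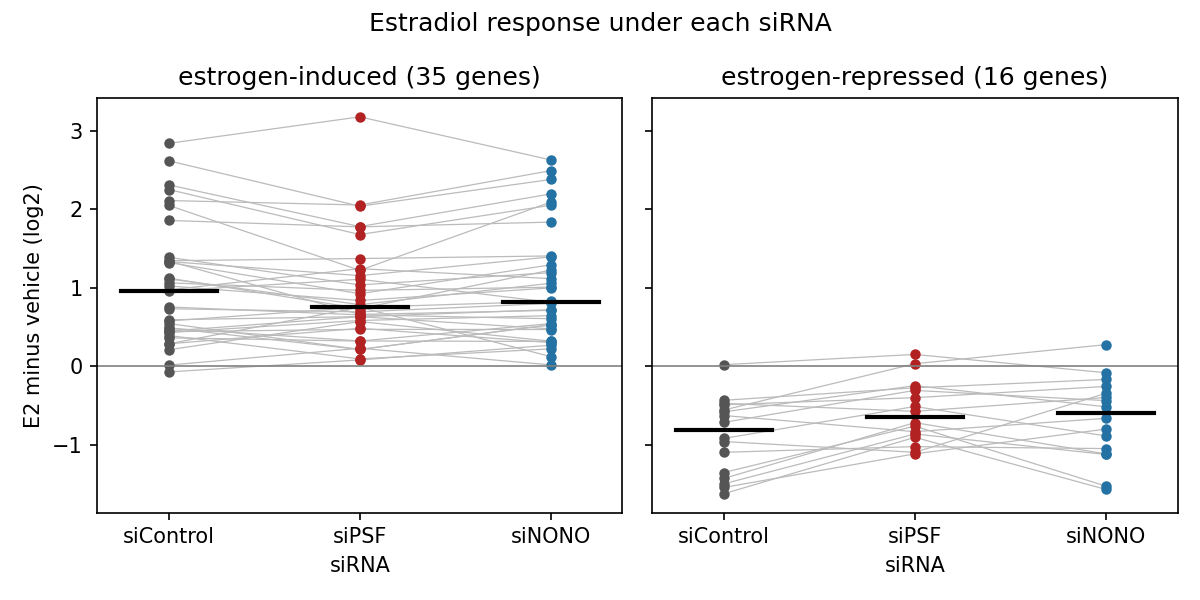
E2 minus vehicle (log2, vertical axis) under each siRNA (horizontal axis) for the 35 estrogen-induced genes on the left and the 16 estrogen-repressed genes on the right. Points are genes, joined by grey lines across siRNAs, and black bars are medians. The induced medians are 0.96, 0.75 and 0.82, and the repressed medians -0.82, -0.65 and -0.59.

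Some genes were called under both knockdowns. Of these, 53 were higher in both and 66 lower in both, against 7.40 and 26.3 for independent lists. In opposite directions, 46 were lower under siPSF and higher under siNONO, against 18.8, and 5 were higher under siPSF and lower under siNONO, against 10.3. Genes higher in both included TP53INP1, EDA2R and PSPC1. Across genes, which are not independent replicates, the correlation of the knockdown effects was 0.208. Unchanged groups simulated with a shared simulated control gave 0.501. The covariance was 0.0119 against a simulated 0.00530, a difference of 0.00656. Part of the overlap may come from the shared controls. With no array in common, siPSF with vehicle against siNONO with E2 correlated at 0.0866, and siPSF with E2 against siNONO with vehicle at 0.0745. Unchanged groups simulated the same way reached at most 0.0300 and 0.0283. The simulated genes varied independently, while real genes can vary together, so these limits may be too narrow and are no measure of chance.

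The remaining lists were called by camera in none of the 4 contrasts, while fry called the basal and mesenchymal list in siNONO minus siControl (adjusted p = 0.0438). The lowest camera adjusted p was 0.33 for paraspeckle components (E2 minus vehicle), 0.206 for interferon-stimulated genes (siPSF minus siControl), and 0.341 for luminal markers (siNONO minus siControl). It was 0.0665 for basal and mesenchymal markers (siNONO minus siControl), 0.35 for hypoxia (E2 minus vehicle), 0.25 for the circadian clock (siPSF minus siControl) and 0.0826 for ribosomal proteins (siPSF minus siNONO). Of 16 paraspeckle components 13 were tested, and NEAT1, FUS and RBMX were not. Single members passed: the prolactin receptor gene PRLR, a luminal marker, fell under siPSF by 1.21 (adjusted p = 0.0107). S100A4, on the mesenchymal list, rose under siPSF by 0.96 (adjusted p = 0.0134) and under siNONO by 1.002 (adjusted p = 0.00849). Interferon genes IFIT1 (1.21), IRF9 (1.10) and RIGI (0.95) rose under siNONO. Of the 23 list calls by camera across the 4 contrasts, 0 held with an estimated correlation and 14 were also called by fry, which tests a list by itself. With 2 residual degrees of freedom, those losses do not show that correlation between genes removed the calls. The long-span list had an estimated correlation of -0.02, below the preset 0.01. Its unadjusted camera p for siPSF minus siControl still rose from 3.61e-15 to 0.0118. Other called lists had estimates above the preset. These were 0.28 for estrogen-repressed genes, 0.24 for mitosis, 0.12 for replication and E2F targets, 0.06 for splicing factors and 0.05 for estrogen-induced genes. For those lists the preset may be too low and their camera p-values too small. In 11 of 64 list tests the median, the mean and the test differed in sign; 0 of those were called.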

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

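The tests of any siRNA against this family, of the siControl arrays, of off-target effects and of compressed differences, and the fit of all probe sets, were chosen only after the result was seen.

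The long-span list had medians of -0.38 under siPSF (17 of 35 lower) and 0.10 under siNONO (4 of 35 higher), and of -0.49 in the direct contrast, siPSF minus siNONO. These 3 camera calls were lost with an estimated correlation (adjusted p = 0.299, 0.321 and 0.299). Random lists matched on expression never reached the siPSF median (percentile 0), which argues against intensity-dependent bias between arrays. The higher of the percentiles in the 2 hormone states was also 0, which argues against one aberrant siPSF array. The labels do not say that the 2 siPSF arrays came from separate cultures, so a difference they share besides the siRNA was not excluded. Under siNONO the median was 0.10, the opposite sign, so a general effect of any siRNA against this family, or of the siControl arrays, does not account for the fall. An off-target effect of the siPSF duplex stays open and cannot be told apart from loss of PSF, since the series has 1 siPSF label.

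Under siNONO 34 of 37 replication and 28 of 29 mitosis genes fell and 15 of 23 p53 targets rose. The 3 list calls were lost with an estimated correlation (adjusted p = 0.313 each). Set against siPSF, which leaves out the siControl arrays, the smallest of the 3 list medians was still 0.37 in size, so those arrays do not account for the pattern. In both hormone states all 3 lists lay 0 percentile points from the end of matched lists. Random genes do not vary together as a co-regulated list can, so that is no measure of chance. With vehicle and E2, the medians were -0.62 and -0.67 for replication, -0.85 and -0.83 for mitosis, and 0.57 and 0.68 for p53 targets. Similar shifts on both siNONO arrays argue against one aberrant array. The labels do not say that these arrays came from separate cultures, so a difference they share besides the siRNA was not excluded. The mitosis median at percentile 0 of lists matched on expression argues against intensity-dependent bias between arrays. An off-target effect of the siNONO duplex stays open and cannot be told apart from loss of NONO, since the series has 1 siNONO label.

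The E2 response of estrogen-induced genes had a smaller median under siPSF. Replication genes, another E2-induced list, kept 0.877 of their mean siControl response, about as low as estrogen-induced genes (0.896). Compression of differences on the siPSF arrays may explain it. A weaker response to E2 would lower both lists as well, so this comparison cannot tell it from compression. Under siNONO, replication genes kept 0.905 and estrogen-induced genes 0.989. Under siPSF, cholesterol synthesis genes, with 1.20 of their mean siControl response, and GREB1 (3.18 against 2.84) went the other way. With the dim filter at the median the siControl and siPSF medians were 0.76 and 0.74. The list difference lay at percentile 0.88 of matched lists, but random genes do not vary together as a co-regulated list can between single arrays. Chance differences between single arrays therefore cannot be told apart from an effect of PSF.

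Other results stood apart between the knockdowns. Estrogen-induced genes differed with a median of -0.19 and the stress response list with 0.23 in siPSF minus siNONO, each with mean differences from siControl of opposite sign; just 7 of 35 and 7 of 20 members passed. Both calls were lost with an estimated correlation (adjusted p = 0.449 each). By fry the stress list was called (adjusted p = 0.0288) and the estrogen-induced list was not (adjusted p = 0.0861). Against siControl the stress list was not called (camera adjusted p = 0.276 for siPSF and 0.277 for siNONO), nor were estrogen-induced genes under siNONO (adjusted p = 0.204). In opposite directions under the knockdowns, 51 genes were called. The mitosis list responded to E2 with a median of -0.021 under siPSF, opposite in sign to siControl; this difference was not tested.

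Probe sets outside the named genes also changed, in the fit of all probe sets above the dim cutoff. Of 1487 with several genes, limma called 17 in siNONO minus siControl, 52 in siPSF minus siNONO and 13 in E2 minus vehicle. Of 7215 without a gene entry, it called 62, 218 and 66. The shares were 1.14%, 3.5% and 0.87% with several genes, and 0.86%, 3.02% and 0.91% without an entry. Those of 1-gene probe sets were higher, at 1.84%, 7.34% and 1.83%. In siPSF minus siControl, 0 of any kind were called.

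For E2 minus vehicle, the real split of the 6 arrays called 1370 genes and the highest of the other 9 splits 0, with 199 to 547 genes at an unadjusted p under 0.05. It was the 1 split of 10 with so many genes, and 10 splits are too few for a share under 0.05. The other splits leave the E2 effect in the residual, and their unadjusted counts lie below the 770.25 genes expected with no effect, so they are no measure of chance.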

How the results depend on the processing

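The all-probe-set fit was chosen after seeing the data; every other alternative was fixed before. Among the targets, study genes, named genes and called lists, no called value changed sign under any alternative run. Other called genes were not checked this way. Named genes were picked for the same direction in every pair of arrays, so leaving out 1 array could hardly reverse them. Counts kept within 1.5 times the main count under quantile normalization, median centring, cyclic loess, the mean of probe sets and robust eBayes. Higher and lower counts follow in that order for siPSF minus siControl, siNONO minus siControl, siPSF minus siNONO and E2 minus vehicle. An intensity trend gave 642 and 1132, 1237 and 1478, 1723 higher, and 1433 and 1141. A dim filter at the median, which tests fewer genes, gave 466 and 909, 952 and 1224 and, for E2, 1173 and 937; no dim filter gave 143 genes higher for siPSF. The 4 arrays of the compared siRNAs gave 111 and 333 for siPSF. Without the hormone covariate, which puts the hormone effect into the residual, counts were 1 and 10, 8 and 23, and 213 and 320; without the siRNA covariate they were 47 and 3 for E2. The fit of all probe sets above the cutoff gave 0 and 0, 69 and 218, 501 and 649, and 195 and 95, all of them among the main calls; the prior degrees of freedom fell from 3.94 to 2.80 and the smallest siPSF adjusted p rose from 0.00743 to 0.0609. Leaving out 1 array left 1 residual degree of freedom, and a lone array was assumed to vary like the others. Counts then ran from 0 to 111 higher and 0 to 333 lower for siPSF, 0 to 412 and 0 to 632 for siNONO, 302 to 792 and 392 to 1038 for siPSF minus siNONO, and 135 to 293 and 56 to 207 for E2. The zeros came without either siControl array or either array of the knockdown, with 2044 to 2883 (siPSF) and 2595 to 2873 (siNONO) genes at an unadjusted p under 0.05 in limma. The called lists ran from 4 to 6, 4 to 6, 5 to 7 and 5 to 6, against 5, 6, 6 and 6 with all arrays. An estimated correlation called 0, 0, 0 and 0 lists, with 1, 3, 3 and 3 at an unadjusted p under 0.05; fry called 1 of the siPSF lists. The 2-fold counts at 1.5-fold became 70 higher and 212 lower for siPSF, 107 and 274 for siNONO, and 130 and 46 for E2; the dim filter at the median left 7 higher for siPSF. That filter also moved the induced E2 response under siControl to 0.76, the repressed response under siNONO to -0.73 and the correlation of the knockdown effects to 0.189. Pairs with no shared array gave 0.0866 and 0.0745. For named, target and study genes, leaving out 1 array ended 221 calls, and 415 results were as before. Among other alternatives 55 calls were lost, 2 gained and 958 results were as before. Results as before include genes that were not called in the main fit either. The cause of these changes was not tested except where stated. Dim genes near the array background limit what could be called.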

Other observations

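The gene classes were chosen, and the SNORD116 genes named, only after their values were seen. Of 59 core histone genes measured, 24 were lower and 1 higher under siNONO and the others did not pass. Their median difference was -0.53, and the class had no set test. Under siPSF 1 of the 59 was lower and the median was -0.02, and the direct contrast, siPSF minus siNONO, called 30 higher and 2 lower. Histone genes have close copies, so their levels are uncertain gene by gene.

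All 3 measured SNORD116 small nucleolar RNAs rose under siPSF, with a median of 1.25, while under siNONO the median was 0.07. The other 139 small nucleolar RNA genes had a median of 0.0796 under siPSF, so a shift of all small nucleolar RNAs on the siPSF arrays does not account for the rise. SNORD116 genes are near-identical copies, so their levels are not 3 independent readings.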
